A study of Mus musculus with 10 samples.

How the data were processed

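Messenger RNA from mouse lung was measured in 10 libraries. The titles place 3 libraries in C, 4 in Hy and 3 in HE. The series title names 3 conditions, namely wild-type mice, mice with pulmonary hypertension induced by hypoxia, and such mice under aerobic exercise. The labels do not spell out which prefix stands for which condition, so the groups keep the names C, Hy and HE. The other labels were identical in all samples. Nothing in them says that the libraries came from separate animals, so the p-values measure only the spread between these libraries, part of which may be technical.

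RNA was extracted with Trizol from powdered tissue and mRNA was selected with oligo(dT) beads, per the labels' protocols. First strands were primed with random hexamers and the libraries were circularised, and the protocol does not state whether strand was kept. Without strand, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as the alpha globin genes, the ribosomal protein genes and the Stfa family, are uncertain. The tools named are HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq 1.4.5, with genome build GRCm38.p6, per the submitters' processing notes. Their roles and the annotation release are not given in the sources used here. The deposited values are estimated counts per gene, not normalised, and between 91.0% and 93.6% of the values in a library were whole numbers. Each library lists 65389 gene identifiers, of which 19204 have a value in at least 1 library.

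The C libraries had values for 18713 genes, and the Hy and HE libraries had values for 17956 genes. The sets shared 17465 genes. Another 1248 genes had values in C alone and 491 in Hy and HE alone. Of the genes valued in C, 1363 were at 0 in all 3 C libraries, whereas no gene valued in Hy and HE was at 0 in all 7 of those libraries. The C libraries were thus tabulated apart from the others, with another gene set. This difference coincides with the group, so a difference between C and Hy or between C and HE cannot be separated from it. Only the comparison of HE with Hy sets no C library against another group. The C libraries still entered its filter, scaling factors, estimate of the spread and choice of shared genes.

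Gene symbols and positions came from a RefSeq gene table on GRCm38.p6, which named 19150 of the 19204 genes with a value. Counts were rounded to whole numbers and the shared genes were tested. Total estimated counts ran from 16560649 in C1 to 17804039 in HE3. After edgeR's filter on low counts, 14766 genes were tested. The 3 groups were fitted together with edgeR 4.0.16 (R 4.3.3), using TMM factors, robust quasi-likelihood dispersion and 7 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, with no fold threshold. The common biological coefficient of variation was 26.9%. Levels are given as TMM-scaled CPM, the usual scaling of counts by library size, as mean ± SD over libraries. Adjusted p-values of genes are from this test unless another tool is named. Where a gene was at 0 in a whole group, its fold is a lower bound against 3 counts per library, which covers counting error only.

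Before the data were examined, 52 gene lists of pathways and cell types were fixed, of which 49 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, then with an estimated correlation and with fry. A list score for a library is the mean over members of log2 CPM minus the member's mean over all libraries. The named genes followed a rule fixed at the same time. For each comparison it took the 6 higher and the 6 lower called genes with the greatest fold change, at least 2 CPM on average, groups that did not overlap and a proper symbol. It added up to 3 members with the smallest p in the direction of the call for each called list. It also took 12 fixed genes, and up to 10 genes called in opposite directions in Hy against C and HE against Hy, of which there were 0.

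The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, no filter, at least 1 CPM in 3 libraries, a 2-fold threshold, only the groups compared, the replicate number as a block, and each library left out. Other settings were added after seeing the data. They were genes that overlap no other gene, all genes with values in Hy and HE, and fits without C1, Hy4 and HE3 or without Hy2 and Hy4. Libraries with the same number in C and Hy deviated together from their group means across genes, with correlations of 0.12, 0.25 and 0.13. By the criterion of 0.1 in every pair the numbers were treated as pairing C with Hy, although the labels state no pairing. C1 correlated at 0.45 with Hy4, and C2 at 0.27 with Hy3. No other library shares the number of Hy4, so the block fits Hy4 exactly. Blocked fold changes and their spread thus take nothing from Hy4, and fewer residual degrees of freedom remain. The criterion was applied after the counts with the block had been seen. Blocked values are given beside results of Hy against C that they change.

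On data simulated for 14766 genes with 100 genes changed at each fold size, the test of Hy against C called 45% of 2-fold and 84% of 4-fold changes, with 5 false calls. For HE against Hy it called 47% and 86%, with 5 false calls, and for HE against C 39% and 86%, with 7 false calls. A list shifted on purpose was called in each of these comparisons. Of 44 unshifted lists, 0, 0 and 2 were called in the simulation. With the real libraries divided between the groups in other ways, camera called up to 24 lists in Hy against C. Such divisions called up to 25 lists in HE against Hy and up to 23 in HE against C. The simulated counts therefore do not give the rate of false list calls in the real libraries. Replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 16.5 or more, so no library was treated as a duplicate. This value ran from 16.5 to 33.1 in C, from 37.9 to 51.0 in HE and from 47.6 to 194.7 in Hy. The simulation gave each gene the same spread in all groups. Its shares of called changes may thus be too high for comparisons with Hy.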

Results

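Lung mRNA was compared between 3 C, 4 Hy and 3 HE libraries. The libraries held from 16560649 (C1) to 17804039 (HE3) estimated counts. Scgb1a1, the secretory protein of club cells in the airway, was the most abundant gene in 9 libraries at 2.83% to 9.17% of counts. In Hy3 it took 1.98%, and Hba-a1, an alpha globin gene of red cells, took 2.95%. Hba-a1 ranged from 0.0532% in Hy4 to 0.695% in Hy2 among the other 9 libraries. On the first principal component, which held 39.3% of the variance, C lay between -67.4 and -46.1, Hy3 at -2.65 and the remaining Hy and HE libraries between 19.6 and 54.7.

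Hy against C addressed the difference between hypoxic and control lungs, if the prefixes are read that way. Camera called the smooth muscle, neutrophil, glycolysis and immediate early lists higher in Hy and the heat shock, unfolded protein response and NK cell lists lower. Each of these 7 lists had an adjusted p = 0.952 with an estimated correlation, and from 2 of 16 to 11 of 19 members passed in the direction of the call. Among all 14766 tested genes, 26.1% were called, 2225 higher and 1625 lower. Bmpr2, the type II receptor for bone morphogenetic proteins (chromosome 1, positions 59764279 to 59878081), fell from 712 ± 105 CPM in C (SD, n = 3) to 343 ± 83.9 CPM in Hy (SD, n = 4). Its log2 fold change was -1.05 (SE 0.19, edgeR adjusted p = 0.00537). Ednrb, the endothelin receptor B gene (chromosome 14, positions 103814615 to 103844508), fell from 122 ± 5.66 to 50.6 ± 10.6 CPM (log2 fold change -1.27, SE 0.28, adjusted p = 0.0118). Slc2a1, which encodes the glucose transporter GLUT1 (chromosome 4, positions 119108745 to 119137330), rose from 19.1 ± 4.02 to 36.8 ± 5.67 CPM (log2 fold change 0.95, SE 0.19, adjusted p = 0.00756). These 3 calls held without each library. Over all alternatives the adjusted p ran from 5.52e-06 to 0.0583 for Bmpr2, from 0.000213 to 0.0977 for Ednrb and from 0.000105 to 0.044 for Slc2a1. The calls of Bmpr2 and Ednrb were lost without Hy2 and Hy4 together (0.0583 and 0.0764) and without C1, Hy4 and HE3 together (0.0566 and 0.0977). Their log2 fold changes ran from -1.25 to -0.93 and from -1.36 to -1.17 over all alternatives. Fits with fewer libraries also have less power, so a call lost in them, here or for other genes, need not mean a smaller change. Every value in this comparison carries the separate tabulation of C.

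Of the 18 smooth muscle genes, 9 rose, 1 (Hhip, noted after its value was seen) fell and 8 did not pass, with 9 and 1 when adjusted over the list alone. Smtn, Tpm2 and Myh11, all parts of the contractile apparatus, rose from 90.2 ± 4.05, 50.1 ± 14.8 and 125 ± 44.5 CPM in C to 169 ± 17.7, 146 ± 45.9 and 355 ± 115 CPM in Hy (adjusted p = 0.00149, 0.00391 and 0.00568). Acta2, smooth muscle actin, rose from 161 ± 66.0 to 323 ± 66.3 CPM (log2 fold change 1.01, adjusted p = 0.0264). The Acta2 call was lost without C2, C3, Hy2 or Hy4 (adjusted p = 0.104, 0.106, 0.0576 and 0.0665), with the replicate block (0.0553), without C1, Hy4 and HE3 together (0.0531) and without Hy2 and Hy4 together (0.177), and its adjusted p ran from 0.00253 to 0.177 over all alternatives. Camera called the list higher (adjusted p = 0.00617), and its adjusted p was 0.952 with an estimated correlation. An exact two-sided permutation test of the list score gave p = 0.114 (adjusted p = 0.509), and the score of C1 (0.07) was above that of Hy3 (-0.01). Within C and within Hy the libraries stood in the same order in the smooth muscle, cardiac muscle, skeletal muscle, adipocyte, club cell and ciliated cell scores, from C1 over C3 to C2 and from Hy4 over Hy1 and Hy2 to Hy3. The cardiac scores were 2.28, -1.10 and -3.33 in C and 2.36, 0.24, -1.04 and -1.63 in Hy, in that order. Without C1, Hy4 and HE3 the smooth muscle list was still called (adjusted p = 8.59e-06, the lowest over all alternatives, with 0.952 the highest).

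Of the 19 neutrophil genes, 11 rose and 8 did not pass, with 15 rising when adjusted over the list alone. Their median log2 fold change was 2.44, and 0.54 with Hy1 and Hy3 alone set against C. S100a8, one subunit of calprotectin (chromosome 3, positions 90669071 to 90670034), rose from 8.41 ± 2.83 to 194 ± 198 CPM, and S100a9, its partner, from 18.5 ± 4.45 to 454 ± 505 CPM (adjusted p = 0.0129 and 0.0141). The SDs in Hy were as large as the means because Hy2 and Hy4 held 285 and 430 CPM of S100a8 against 40.4 in Hy1 and 20.5 in Hy3. The S100a8 call was lost without C2 or C3 (adjusted p = 0.0508 and 0.0568) and with the replicate block (0.0583), and the S100a9 call without C2 or C3 (0.0548 and 0.0596). Over all alternatives the adjusted p of S100a8 ran from 1.71e-05 to 0.102 and that of S100a9 from 2.71e-05 to 0.107. Stfa2l1, a stefin gene, rose from 0.668 ± 0.286 to 13.4 ± 13.3 CPM (adjusted p = 0.0118), and lost its call without C1 or C3 (0.0501 and 0.0535) and with limma-voom (0.102, with a range of 1.13e-06 to 0.136 over all alternatives). Without C1, Hy4 and HE3 together none of these 3 genes was called (0.102, 0.107 and 0.136). Camera called the list higher (adjusted p = 0.00153), and its adjusted p was 0.952 with an estimated correlation. The permutation test gave p = 0.0571, the smallest that 3 and 4 libraries allow, and 0.311 after adjustment over the 49 lists. The glycolysis, immediate early, heat shock and unfolded protein response scores gave the same 2 values. So did the MHC class II, complement and acute phase, general capillary endothelium and T cell scores, whose lists camera did not call.

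**Figure D1:**
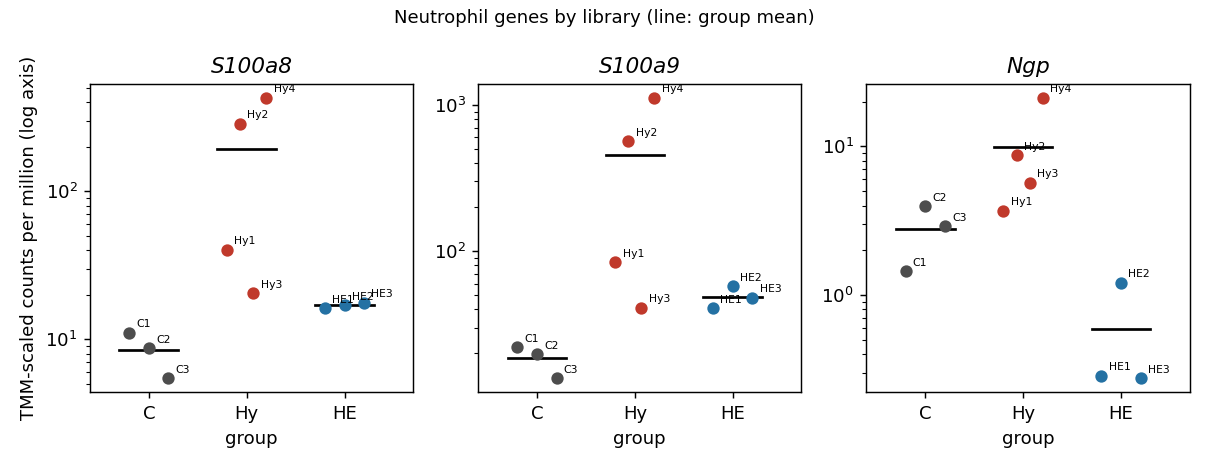
TMM-scaled CPM of 3 neutrophil genes on a log axis, with a point per library of C, Hy and HE and a line at each group mean. For S100a8, Hy2 and Hy4 held 285 and 430 CPM, and the other 8 libraries held 5.46 to 40.4 CPM.

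Of the 23 immediate early genes, which respond within minutes to many stimuli, 8 rose and 15 did not pass, with 10 rising when adjusted over the list alone. Jund, Junb and Klf4, all transcription factor genes, rose by 1.76, 2.18 and 1.34 on the log2 scale (adjusted p = 0.000836, 0.00174 and 0.00238). Camera called the list higher (adjusted p = 0.000382). With an estimated correlation the adjusted p was 0.952, and fry gave an adjusted p of 0.0423, its only call in 3 comparisons. Of the 13 glycolysis genes, 6 rose and 7 did not pass, with 6 when adjusted over the list alone. Aldoa, which encodes aldolase A, rose from 433 ± 38.9 to 937 ± 172 CPM (adjusted p = 0.00258, within 6.48e-09 to 0.0527 over all alternatives), and lost its call without C1, Hy4 and HE3 together (0.0527). Gapdh and Pfkl rose by 0.69 and 1.26 on the log2 scale (adjusted p = 0.0138 and 0.0144). Gapdh lost its call without C2 or C3 (0.0674 and 0.0599) and with the replicate block (0.065), and Pfkl without C2 or C3 (0.051 and 0.0598). Both lost it without C1, Hy4 and HE3 together (0.0819 and 0.126) and without Hy2 and Hy4 together (0.109 and 0.0829), and their adjusted p ran from 0.00024 to 0.109 and from 0.000471 to 0.126 over all alternatives. Camera called the list higher at an adjusted p of 0.0448, with 0.952 as the adjusted p with an estimated correlation. This list call was lost without C2, C3, Hy2 or Hy3 (adjusted p = 0.093, 0.0669, 0.096 and 0.18), with RLE factors (0.0507), with the replicate block (0.0539), on genes that overlap no other gene (0.086), without Hy2 and Hy4 together (0.0935) and with fry (0.098), within a range of 0.00318 to 0.952 over all alternatives.

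Of the 16 heat shock genes, 8 fell and 8 did not pass, with 9 falling when adjusted over the list alone. Their median log2 fold change was -1.22. Hsp90aa1, an inducible HSP90 gene, fell from 1260 ± 133 to 422 ± 83.6 CPM and Hspd1, a mitochondrial chaperonin gene, from 233 ± 25.9 to 96.5 ± 19.0 CPM (adjusted p = 0.0111 and 0.00682, within 6.45e-05 to 0.0828 and 2.08e-05 to 0.074 over all alternatives). Both calls were lost without C1, Hy4 and HE3 together (0.0828 and 0.074), and that of Hsp90aa1 without Hy2 and Hy4 together (0.0775). Hspa4l had a log2 fold change of -1.42 (adjusted p = 0.0167), a call lost without C2 or C3 (0.0571 and 0.0524), with the replicate block (0.0552) and without C1, Hy4 and HE3 together (0.106, within 0.00054 to 0.106 over all alternatives). Of the 22 unfolded protein response genes, 8 fell, 1 (Atf4, noted after its value was seen) rose and 13 did not pass, with 11 and 1 when adjusted over the list alone. Asns, Canx and Pdia3 had log2 fold changes of -0.95, -0.87 and -0.90 (adjusted p = 0.00154, 0.00281 and 0.00575). Canx and Pdia3 lost their calls without C1, Hy4 and HE3 together (0.0614 and 0.087, within 3.76e-08 to 0.0614 and 3.25e-06 to 0.087 over all alternatives). Asns makes asparagine, Canx encodes calnexin and Pdia3 a protein disulfide isomerase. Of the 16 NK cell genes, 2 fell and 14 did not pass, with 0 when adjusted over the list alone, where edgeR gave Ncr1, Gzmb and Klri2 unadjusted p-values of 0.00328, 0.0122 and 0.0209. Ncr1, an NK cell receptor gene, went from 6.91 ± 0.577 to 2.67 ± 1.24 CPM (adjusted p = 0.0212). It lost its call without C1, C2 or C3 (0.0582, 0.0722 and 0.0582), without C1, Hy4 and HE3 together (0.116) and without Hy2 and Hy4 together (0.0694), within 0.00197 to 0.116 over all alternatives. Gzmb was called at an adjusted p of 0.0481 and lost the call without C1, C2, C3, Hy2, Hy4, HE1 or HE2 (0.0604 to 0.122) and with the replicate block (0.117). It also lost it with no filter (0.0544), with only the 2 groups compared (0.0699), without C1, Hy4 and HE3 together (0.207) and without Hy2 and Hy4 together (0.235, within 0.0183 to 0.235 over all alternatives). Klri2 was not called (0.0685), but DESeq2, limma-voom and edgeR without Hy1 called it (0.0449, 0.0476 and 0.0292, within a range of 0.0292 to 0.272 over all alternatives). Camera called the heat shock, unfolded protein response and NK cell lists lower (adjusted p = 0.000206, 0.000206 and 0.0223). All 3 had an adjusted p of 0.952 with an estimated correlation. The NK cell list lost its call without C3, Hy2 or Hy3 (adjusted p = 0.0591, 0.118 and 0.139, within 0.000214 to 0.952 over all alternatives), and without Hy2 and Hy4 together (0.196). Its score was 0.86 in Hy1, within the 0.59 to 0.99 of the C libraries, and at most -0.16 in the other 3 Hy libraries. The permutation test of this score gave p = 0.171 (adjusted p = 0.56).

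Among the other fixed genes, Nos3, which encodes endothelial nitric oxide synthase, rose from 28.9 ± 7.99 to 68.2 ± 30.2 CPM (log2 fold change 1.24, adjusted p = 0.0314). That call was lost without C1, C2, C3, Hy2 or Hy3 (adjusted p = 0.107, 0.0556, 0.0952, 0.0734 and 0.0538) with the replicate block (0.0634), with only the 2 groups compared (0.0543), without C1, Hy4 and HE3 together (0.163) and without Hy2 and Hy4 together (0.133), within a range of 0.0042 to 0.163 over all alternatives. Edn1, Vegfa, Col1a1, Eln, Apln and Kcnk3 did not pass, with log2 fold changes of -0.45, 0.17, -0.27, 0.33, -0.04 and 0.64. Hba-a1 averaged 10765 ± 13874 CPM in Hy and 2404 ± 578 CPM in C (adjusted p = 0.146, or 0.0487 without Hy4, within 0.0487 to 0.515 over all alternatives).

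**Figure D2:**
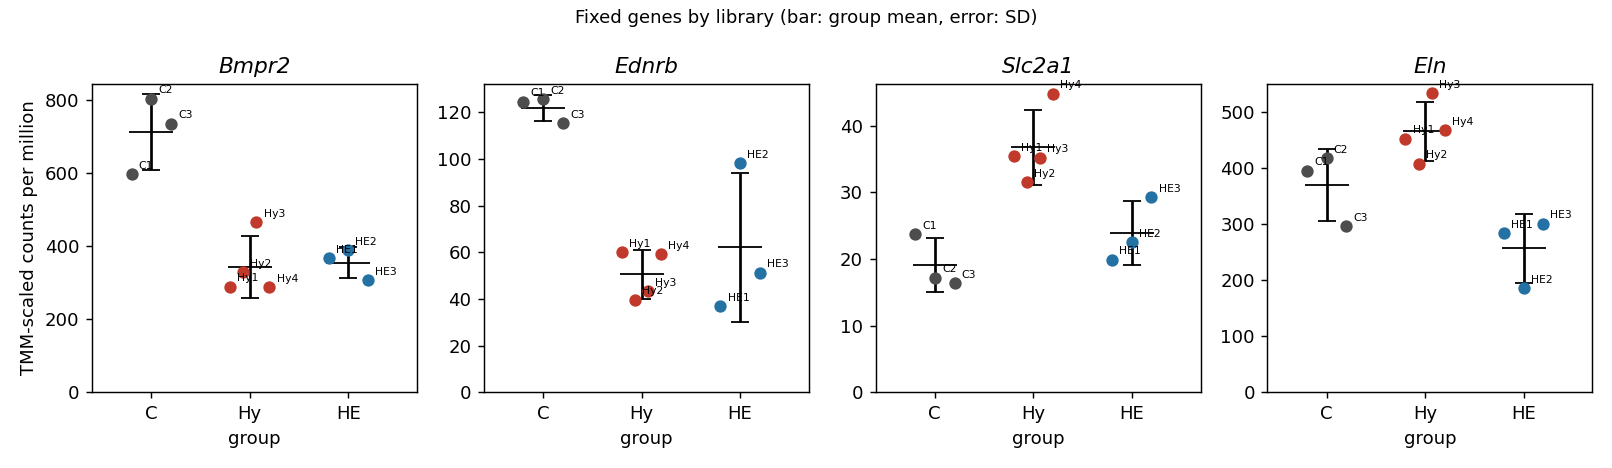
TMM-scaled CPM of 4 fixed genes, with a point per library, the group mean as a bar and the SD as its error. Bmpr2 averaged 712 CPM in C, 343 in Hy and 354 in HE, and Eln averaged 369, 465 and 257 CPM.

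Among the genes with the greatest fold changes, several were close to 0 in C or in Hy. Rpl29, a ribosomal protein gene (chromosome 9, positions 106428889 to 106431568), had 0.738 ± 0.182 CPM in C and 762 ± 236 CPM in Hy. Rpl32l was at 0 in all C libraries and at 20.6 ± 6.16 CPM in Hy, at least 120-fold higher. Mia2 and Anks1b rose from 0.358 ± 0.159 and 0.0938 ± 0.116 CPM to 73.6 ± 5.44 and 26.1 ± 6.16 CPM. Gpr17, Klhl10, Rpl31-ps12, Mmp24, Rpl37rt and Cerkl had log2 fold changes of -8.22, -8.11, -6.99, -6.10, -5.91 and -5.52. Of the genes named in this paragraph, only Rpl29 and Rpl37rt had a value in all 21 alternatives, genes that overlap no other gene included. The separate tabulation of C bears on all of these values. Of the 49 genes at least 32-fold apart, 28 overlapped another gene, where reads moved between gene models stay open. Psca and Cstdc5 were called at adjusted p of 0.0495 and 0.0189, and each lost its call without C1, C2 or C3 (0.125, 0.119 and 0.14 for Psca, 0.0678, 0.0724 and 0.0565 for Cstdc5). Psca also lost it without Hy2, Hy4, HE1 or HE3 (0.119, 0.0681, 0.0635 and 0.0632), with limma-voom (0.29), with no filter (0.0732), without C1, Hy4 and HE3 together (0.215) and without Hy2 and Hy4 together (0.403). Cstdc5 also lost it with limma-voom (0.102) and without C1, Hy4 and HE3 together (0.171). With the replicate block the adjusted p was 0.193 for Psca and 0.0697 for Cstdc5, and over all alternatives it ran from 0.00256 to 0.403 and from 0.00305 to 0.171.

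In all, edgeR called 2225 genes higher and 1625 lower in Hy than in C, which is 26.1% of 14766. Of these, 803 and 331 had at least a 2-fold change, and 49 differed at least 32-fold. The groups did not overlap in 4967 genes, or 33.6%, where chance gives 5.71%. With the replicate block, 1112 genes were higher and 633 lower. The block in effect leaves out Hy4, and without Hy4 alone 1513 genes were higher and 945 lower. The 3850 calls became 1972, 1681 and 1690 without C1, C2 and C3, 2737 and 2458 without Hy2 and Hy4 each, and 5973 without Hy3. Without C1, Hy4 and HE3, the library of each group with the highest cardiac muscle score, 360 genes were called, and 1070 without Hy2 and Hy4.

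HE against Hy addressed exercise in hypoxic mice under the same reading of the prefixes, and both groups were tabulated alike. No single gene passed the test. The clearest difference was in the 19 neutrophil genes, 18 of which were lower in HE, with a median log2 fold change of -2.47. S100a8 averaged 16.96 ± 0.75 CPM in HE (SD, n = 3) and 194 ± 198 CPM in Hy (SD, n = 4). Ngp, a granule protein gene (chromosome 9, positions 110419808 to 110423012), averaged 0.592 ± 0.537 CPM in HE and 9.84 ± 7.89 CPM in Hy. Its log2 fold change was -4.06 (SE 0.78, edgeR adjusted p = 0.597). Stfa2l1 had 1.27 ± 0.256 and 13.4 ± 13.3 CPM. DESeq2 called S100a8, Ngp and Stfa2l1 (adjusted p = 0.0415, 1.91e-05 and 0.00788), the lowest over their alternatives, the highest being 1.00 for each. None of the 19 genes passed over all genes, and 18 passed in the lower direction when adjusted over the list alone. Camera called the list lower (adjusted p = 1.66e-23), with an adjusted p of 0.343 with an estimated correlation. The exact permutation test of the score gave p = 0.0571, the smallest possible, and an adjusted p of 0.958. The platelet score also gave 0.0571, the other 14 lists called in this comparison gave 0.114 to 0.629, and the adjusted p was 0.958 for all. Hy2 and Hy4 had neutrophil scores of 2.00 and 2.803, and the other 8 libraries had -1.13 to -0.12. With Hy1 and Hy3 alone set against HE, the median was -0.40.

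Platelet and megakaryocyte genes and immediate early genes were also lower in HE as lists (camera adjusted p = 2.88e-08 and 1.58e-06), each with an adjusted p of 0.343 with an estimated correlation. Their median log2 fold changes were -0.61 and -0.39, and 0 of 18 and 0 of 23 members passed, also when adjusted over the list alone. At an unadjusted edgeR p below 0.05, examples were Treml1, Ppbp and Gp1bb of platelets and Atf3, Nr4a3 and Myc of the immediate early list. Ppbp, a platelet chemokine gene, had 4.80 ± 1.29 CPM in HE and 8.86 ± 2.41 CPM in Hy. Atf3 had 8.37 ± 1.26 and 21.0 ± 13.9 CPM.

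The other lists called lower in HE were those of NK cells, red cells, interstitial macrophages and monocytes, dendritic cells, and cytokines and chemokines (camera adjusted p = 0.000476, 0.000505, 0.00152, 0.00391 and 0.00391). With an estimated correlation the adjusted p was 0.683, 0.664, 0.64, 0.664 and 0.401. When adjusted over the list alone, Socs3 and Il1b of the 29 cytokine genes and Treml4 of the 22 macrophage genes passed, all lower. Socs3, a feedback inhibitor of cytokine signalling, had 44.1 ± 3.45 CPM in HE and 93.0 ± 20.1 CPM in Hy (log2 fold change -1.08, edgeR adjusted p = 0.597, DESeq2 adjusted p = 0.000219). Without Hy3 edgeR called it (0.0434), and over all alternatives its adjusted p ran from 0.000219 to 1.00. Il1b had 9.06 ± 5.16 and 38.3 ± 23.2 CPM, Ccr2, a monocyte chemokine receptor gene, 8.76 ± 2.63 and 25.8 ± 19.4 CPM, and Treml4 3.68 ± 0.173 and 7.96 ± 2.39 CPM. DESeq2 called Il1b and Treml4 (adjusted p = 0.0133 and 0.0461, the lowest over their alternatives, with 1.00 the highest). Each of these list calls depended on a library. NK cells lost it without Hy1 or HE3 (adjusted p = 0.436 and 0.0509), red cells without Hy3 (0.537), macrophages without Hy2 (0.0965), dendritic cells without Hy1 or HE2 (0.497 and 0.0558), and cytokines without Hy1 (0.0961). On genes that overlap no other gene, macrophages, dendritic cells and cytokines were not called (0.0556, 0.112 and 0.349), nor were macrophages without Hy2 and Hy4 together (0.0811). Over all alternatives, fry included, the adjusted p ran from 3.19e-05 to 0.79 for macrophages, 7.64e-05 to 0.79 for dendritic cells and 0.000564 to 0.725 for cytokines. Hy3 held the most Hba-a1 of all libraries.

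Camera called 8 lists higher in HE, where the adjusted p ranged from 0.401 for the clock to 0.828 for oxidative phosphorylation and the unfolded protein response with an estimated correlation. They were the lists of fatty acid oxidation, adipocytes, the circadian clock, nuclear oxidative phosphorylation and alveolar type 1 cells (adjusted p = 0.000476, 0.00142, 0.00152, 0.00155 and 0.00391), and those of the unfolded protein response, arterial endothelium and glucocorticoid-responsive genes (0.0106, 0.0387 and 0.0495). No member of these 8 lists passed over all genes or when adjusted over the list alone. Hlf, a clock-controlled transcription factor gene, had 38.3 ± 8.23 CPM in HE and 15.4 ± 6.71 CPM in Hy (log2 fold change 1.31, edgeR adjusted p = 0.739). Igfbp2, a marker of alveolar type 1 cells, had 698 ± 42.0 and 323 ± 84.5 CPM (edgeR adjusted p = 0.739, DESeq2 adjusted p = 0.0498, with a range of 0.0498 to 1.00 over all alternatives). Mgp, an inhibitor of calcification in arteries, had 1109 ± 109 and 652 ± 199 CPM, and Hadh, an enzyme of fatty acid oxidation, 89.3 ± 1.55 and 71.4 ± 6.46 CPM. Adipoq, which encodes adiponectin, ranged from 0.242 to 15.2 CPM in HE and from 0 to 0.788 CPM in Hy.

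Leaving out 1 library ended each of these 8 calls at least once. Fatty acid oxidation was lost without HE2 (adjusted p = 0.0558), adipocyte without Hy3 or HE3 (0.1 and 0.0549), the clock without Hy1 (0.0795), oxidative phosphorylation without Hy3 or HE3 (0.853 and 0.207), and alveolar type 1 without Hy2 or HE3 (0.173 and 0.0765). The alveolar type 1 list was also lost without C1, Hy4 and HE3 together (0.245), without Hy2 and Hy4 together (0.744) and on genes that overlap no other gene (0.0626, within 7.64e-05 to 0.79 over all alternatives). The unfolded protein response was lost without Hy1, Hy3 or HE1 (0.0552, 0.383 and 0.429, with the direction turned without HE1), with the replicate block (0.0531) and on genes that overlap no other gene (0.0775, within 4.29e-06 to 0.861 over all alternatives). Arterial endothelium was lost without Hy1, Hy3, Hy4, HE1 or HE2 (0.0961, 0.13, 0.114, 0.203 and 0.0558), with the replicate block (0.0554) and on genes that overlap no other gene (0.0929, within 0.00553 to 0.79 over all alternatives). Glucocorticoid-responsive genes were lost without C3, Hy1, Hy2, Hy4, HE2 or HE3 (0.0503, 0.232, 0.0909, 0.135, 0.821 and 0.0681, with the direction turned without HE2). They were also lost with the replicate block (0.17), on genes that overlap no other gene (0.709), without C1, Hy4 and HE3 together (0.203) and without Hy2 and Hy4 together (0.373, within 7.18e-08 to 0.861 over all alternatives). None of the 8 calls was made with fry (0.76 to 0.861). Cardiac muscle markers were high in C1, Hy4 and HE3, where Myh6 reached 633, 1301 and 794 CPM, against 11.1 to 282 CPM elsewhere.

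**Figure D3:**
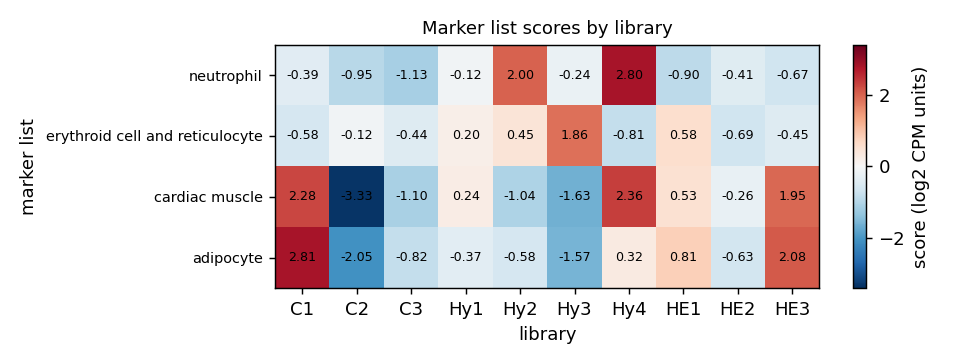
Scores of 4 marker lists in each library, in log2 CPM units relative to the mean over the 10 libraries, with red for higher and blue for lower. Neutrophil scores were highest in Hy2 and Hy4 (2.00 and 2.803), the red cell score in Hy3 (1.86), and cardiac scores in C1, Hy4 and HE3 (2.28, 2.36 and 1.95).

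Among the fixed genes, Eln, which encodes elastin (chromosome 5, positions 134702595 to 134747368), had 257 ± 61.9 CPM in HE and 465 ± 52.0 CPM in Hy, with no overlap between the groups (log2 fold change -0.86, SE 0.20, edgeR adjusted p = 0.687, DESeq2 adjusted p = 0.0119, with a range of 0.0119 to 1.00 over all alternatives). Slc2a1 had 23.9 ± 4.82 and 36.8 ± 5.67 CPM (log2 fold change -0.62, edgeR adjusted p = 0.739). Bmpr2 had 354 ± 42.3 and 343 ± 83.9 CPM, a log2 fold change of 0.05 (SE 0.19). Edn1, Nos3, Vegfa, Ednrb, Acta2, Col1a1, Apln, Kcnk3 and Hba-a1 had log2 fold changes of 0.24, -0.44, -0.05, 0.30, -0.40, -0.20, -0.65, 0.25 and -1.85. Without HE2 the values of Edn1, Ednrb and Kcnk3 turned to -0.12, -0.20 and -0.12. Without Hy3 those of Apln and Hba-a1 were -0.38 and -0.41.

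Between HE and Hy, edgeR called 0 genes, with a smallest adjusted p of 0.597 and 734 genes at an unadjusted p below 0.05 where chance gives 738.3. Fitted on HE and Hy alone, edgeR also called 0 of 14523 genes, with a smallest adjusted p of 0.999956 and 529 genes at an unadjusted p below 0.05. DESeq2 called 9 genes higher and 42 lower (880 unadjusted), and limma-voom called 0 (641 unadjusted). The groups did not overlap in 665 genes, or 4.50%, where chance gives 5.71%. Named after their values were seen, Socs3, Coro1a, Lsp1, Slfn2, Lrrc25 and Cyth4 were called lower without Hy3 (edgeR adjusted p = 0.0434 each), H2-Bl higher without HE1 (0.0212) and Ptgs2 lower without Hy2 and Hy4 together (0.031).

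HE against C compared exercised hypoxic with control lungs under that reading, again across the separate tabulation. Camera called the heat shock, NK cell, dendritic cell and unfolded protein response lists lower in HE, each with an adjusted p = 0.996 with an estimated correlation. Fry called none of them (adjusted p = 0.125 for 3 and 0.195 for the unfolded protein response). Bmpr2 fell from 712 ± 105 to 354 ± 42.3 CPM (log2 fold change -1.01, SE 0.21, edgeR adjusted p = 0.0113), and this call held without each library but was lost without C1, Hy4 and HE3 together (0.0682, within 6.73e-05 to 0.0682 over all alternatives). Clec9a, a receptor of cross-presenting dendritic cells (chromosome 6, positions 129408862 to 129424764), fell from 34.6 ± 5.53 to 1.35 ± 0.235 CPM (log2 fold change -4.67, SE 0.52, adjusted p = 0.000801). Clec9a had a value in 20 of the 21 alternatives. Ccl22 of the same list had one in all 21, genes that overlap no other gene included. Whether the separate tabulation of C contributes to the fall of Clec9a was not tested.

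Of the 16 heat shock genes 6 fell, of the 16 NK cell genes 6 fell, of the 18 dendritic cell genes 5 fell and 1 (Cacnb3, noted after its value was seen) rose, and of the 22 unfolded protein response genes 5 fell. When adjusted over the list alone, the numbers falling were 8, 10, 6 and 5. Among all tested genes, 20.4% were called in HE against C. Hsp90aa1 had 397 ± 266 CPM in HE and 1260 ± 133 CPM in C, with 704 CPM in HE1 and 242 and 245 CPM in HE2 and HE3. Its log2 fold change was -1.67, and -2.38 without HE1. The summed CPM of the heat shock genes was 9806 in HE1 and in C1, 11643 and 12187 in C2 and C3, and 3817 and 3464 in HE2 and HE3. That of the unfolded protein response genes was 5557 in HE1, above all C libraries (5165 to 5372), and 3365 and 3589 in HE2 and HE3. Gzma, a granzyme gene of NK cells, had 6.10 ± 2.43 and 19.5 ± 4.00 CPM, and Ncr1 1.84 ± 0.465 and 6.91 ± 0.577 CPM. Ccl22, a dendritic cell chemokine gene, had 0.958 ± 0.262 and 4.73 ± 0.924 CPM. Asns had 18.2 ± 2.87 and 38.6 ± 2.94 CPM (adjusted p = 0.00165). Camera called the 4 lists lower (adjusted p = 0.000103, 0.000122, 0.0118 and 0.0118), each with an adjusted p of 0.996 with an estimated correlation. The permutation test of the scores gave p = 0.1, the smallest that 3 and 3 libraries allow, for 3 of them and 0.2 for the unfolded protein response (adjusted p = 0.507 for all). The glycolysis, cytokine, MHC class II, pericyte, venous endothelium and interstitial macrophage scores also gave 0.1, and camera did not call their lists. Over genes that overlap no other gene, the dendritic cell list was not called (adjusted p = 0.282, within 0.00232 to 0.996 over all alternatives).

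Of the 26 named genes called here, 13 kept their call without each library and 13 did not. The calls of Ncr1 and Ccl22 were lost without HE2 (adjusted p = 0.0548 and 0.0507), and that of Hsp90aa1 without C2, C3 or HE2 (0.0552, 0.0514 and 0.062). Gzma lost its call without C1, C2, C3, HE2 or HE3 (0.0657, 0.0564, 0.092, 0.0806 and 0.0817). Without C1, Hy4 and HE3 together, Hsp90aa1, Ncr1, Ccl22 and Gzma were not called (0.0993, 0.0962, 0.0768 and 0.163). Ednrb, at 62.2 ± 32.02 and 122 ± 5.66 CPM, was called at an adjusted p of 0.0494, and lost the call without C1, C2, C3, Hy1, Hy2, Hy4, HE1 or HE3 (0.0545 to 0.139). It also lost it with no filter (0.0505), with only the 2 groups compared (0.0594), with the replicate block (0.0672), without C1, Hy4 and HE3 together (0.249) and without Hy2 and Hy4 together (0.0606, within 0.0114 to 0.249 over all alternatives). Nos3, Slc2a1, Acta2, Eln and Kcnk3 did not pass, with log2 fold changes of 0.80, 0.32, 0.61, -0.52 and 0.89. DESeq2 called Eln and Kcnk3 (adjusted p = 0.0423 and 0.0317, within 0.0423 to 0.273 and 0.0217 to 0.265 over all alternatives). Kcnk3 was also called with the replicate block (0.0217), with only the 2 groups compared (0.0445), without Hy3 or Hy4 (0.0426 and 0.0423) and without both Hy2 and Hy4 (0.0459), and Acta2 without C1 (0.045, within 0.045 to 0.396). Apln, with a log2 fold change of -0.69, was called without HE3 alone (0.042, within 0.042 to 0.409).

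The greatest fold changes fell on much the same genes as in Hy against C. Rpl29 had 734 ± 53.1 CPM in HE, and Mia2, Anks1b and Ccl27b rose by 7.60, 7.69 and 5.26 on the log2 scale. Rpl32l was at least 106-fold higher in HE than in C, where it was at 0. Rpl31-ps12, Entpd4 and Gpr17 were at 0 in all HE libraries and at least 82.6-fold, 65.8-fold and 38.6-fold lower than in C. Entpd4 lost its call without C2, C3, HE1 or HE2 (adjusted p = 0.0522, 0.0541, 0.0551 and 0.06), and without C1, Hy4 and HE3 together (0.107). Ntrk2, a neurotrophin receptor gene, rose from 14.3 ± 3.79 to 345 ± 196 CPM (adjusted p = 0.0298), a call lost without any 1 of the 6 libraries compared (0.0539 to 0.0973), with limma-voom (0.0744), with the replicate block (0.0716), without C1, Hy4 and HE3 together (0.15) and without Hy2 and Hy4 together (0.0537, within 0.000787 to 0.15 over all alternatives).

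EdgeR called 1734 genes higher and 1279 lower in HE than in C, of which 614 and 314 changed at least 2-fold. The groups did not overlap in 7627 genes, or 51.7%, where chance gives 10%. The 3013 calls became 1305, 1175 and 1014 without C1, C2 and C3, 1482, 1019 and 1889 without HE1, HE2 and HE3, and 4712 without Hy3. Without C1, Hy4 and HE3, 498 genes were called. Fitted on HE and C alone, 2667 genes were higher and 2741 lower, so higher calls were 49.3% of all, against 57.6% in the fit of 3 groups.

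Of the calls in Hy against C and HE against C, 1516 higher and 1029 lower genes were shared, where independent lists of those sizes would share 261.3 and 140.8. Unchanged groups simulated against the same C libraries had 0 to 1 calls in Hy against C and 0 in HE against C, so they could share none and give no number of shared calls to set beside these. The fold changes of both comparisons correlated at 0.869 across genes, against 0.532 in the simulation, with a covariance of 0.568 against 0.0759. The simulated groups shared the C libraries too, so their correlation and covariance already hold what sharing adds at the simulated spread. The numbers for independent lists take no account of the sharing. The separate tabulation of C enters both comparisons as well and cannot be told apart here from an effect common to Hy and HE. The C libraries were not split between the comparisons, so a larger contribution from sharing them was not tested.

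Genes called in opposite directions in Hy against C and HE against Hy numbered 0 with edgeR, although 5945 and 734 genes had an unadjusted p below 0.05. DESeq2 gave 27 such genes and limma-voom 0. EdgeR gave 6 without Hy3 and 1 without HE1, the genes named for HE against Hy. The covariance of these fold changes was -0.107, where unchanged groups sharing the Hy libraries gave -0.0564 (range -0.0644 to -0.0508). The correlation was -0.31 across genes against -0.42 in that simulation. With Hy split so that the comparisons shared no library, the correlation lay between -0.20 and 0.12 over 6 assignments. In 5 of them HE against Hy had 0 calls, so opposite calls could not arise. With Hy1 and Hy3 set against C and Hy2 and Hy4 against HE, 226 and 93 genes were called, 0 of them in opposite directions.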

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

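The tests in this part of blood content, tissue content, gene overlap and batch were chosen only after the results were seen. The counts over other splits of the libraries were planned.

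Among 117 results with a gap test in the 4 Hy libraries, 5 had a library far from the other 3, and chance gives about 1 in 20, or 5.85. Psca was at 15.6 CPM in Hy2 against at most 1.94 CPM in the others, and Ccl22 at 4.12 CPM in Hy1 against at most 1.56. Bpgm, an enzyme of red cells, was at 86.9 CPM in Hy3 against 35.6 to 36.2 CPM. Gpr17 was at 0.059 CPM in Hy2 and 0 in the others. The arterial endothelium score was 0.210 in Hy2 against at most -0.04 in the others. Genes outside the shared set also carried signal. Gm38947 averaged 341 counts among genes with values in C alone, and Gm15501 averaged 4018 counts among genes with values in Hy and HE alone.

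The first pattern is the large number of genes called between C and the other groups. Movement of reads between genes that overlap in the RefSeq table is not the whole source of the 3850 calls in Hy against C. Genes that overlap no other gene there were called 1.03 times as often as the rest (26.4% of 7826 against 25.6% of 6925). Of the 49 genes at least 32-fold apart, 20 overlapped no other gene in that table, and 1 had no position. This argues against movement between genes that overlap there for the 20. The gene models behind the deposited counts are not given, so movement between models of another extent stays open for all 49. For the 28 that overlapped a gene, movement between the overlapping genes stays open too. Of these 28, 0 overlapped a gene with values in one set only, and the odds ratio of 0 among overlapping genes has an upper limit of 3.53. Of the 49, 4 had ribosomal protein symbols, against 94 of the 14766 tested genes, which is a larger share. Of those 94, 45 were called in Hy against C, also a larger share than the 26.1% of all tested genes. Reads shared with near-identical copies were not tested and stay open. A batch cannot be told apart from the group, since 0 of the 3 C libraries had the gene set of Hy and HE, and an effect of the condition stays open as well.

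In Hy against C, 2 of 35 splits of the 7 libraries called as many genes as the real 3850, so chance cannot be excluded at 0.05. The other split, with 4332 calls, put Hy3 with the C libraries and points to a structure in which Hy3 stands apart from Hy1, Hy2 and Hy4. It parted 2 of the 3 same-numbered pairs, and the 7 other splits that parted all 3 pairs called at most 0 genes. For HE against C the 10 possible splits are too few for a share under 0.05, with 3013 genes in the real split and 0 in the highest other. For HE against Hy the real counts of called genes and of genes with opposite calls were both 0, which all 35 splits reach by construction, so these counts say nothing about chance. The highest others were 31 and 4, both in the split that set Hy3 with HE. The list calls did not stand out from other splits. In Hy against C, 34 of 35 splits called at least the real 7 lists, with up to 24, and in HE against Hy, 24 of 35 called at least the real 16, with up to 25. In HE against C, 10 of 10 splits called at least the real 4 lists, with up to 23, and 10 splits are too few for a share under 0.05.

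The second pattern is the neutrophil list, high in Hy2 and Hy4. More blood left in the tissue would bring globin mRNA along with neutrophils. In Hy4, which had the highest neutrophil score, Hba-a1 took 0.0532% of counts, below the lowest C library (0.194%). In Hy2 it took 0.695%, above the highest C library (0.304%). From the highest C library the neutrophil score rose by 3.19 in Hy4 and 2.39 in Hy2, and from the lowest C library Hba-a1 went by -1.87 and 1.84 on the log2 scale. HE2, whose neutrophil score was not above C1, had a gap of 0.57 between these values. The gap of 5.06 in Hy4 is beyond that and argues against more blood of the composition in C as the whole source there. The gap of 0.55 in Hy2 is not, so blood content stays open for that library. Hy3 and HE1 took 2.95% and 0.54% of counts in Hba-a1 with neutrophil scores of -0.24 and -0.90. Blood with a larger share of neutrophils than in C stays open for both libraries, as do an effect of the condition on neutrophils in the tissue, an untested hypothesis, and variation between libraries of that group.

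The third pattern is the higher fatty acid oxidation and adipocyte lists in HE than in Hy, weighed against heart or fat tissue in C1, Hy4 and HE3. Without these libraries the median log2 fold change of fatty acid oxidation was 0.31, against 0.16 with them. The list scores of Hy4 and HE3 were 0.11 and 0.09, and that of Hy4 was the highest in Hy. Leaving out both could thus hardly lower the difference. The difference was present without these libraries, but the refit could not test what tissue in them added. Camera still called the list (adjusted p = 3.14e-06), with an adjusted p = 0.484 with an estimated correlation, and 0.664 with all libraries (range 3.14e-06 to 0.79 over all alternatives). The call with all libraries was lost without HE2 (0.0558), whose score was 0.35 against -0.03 in HE1 and -0.24 to -0.10 in Hy1, Hy2 and Hy3. The adipocyte median went from 1.27 to 0.49, under the bound set for tissue content, and fat attached to HE3 may account for part of it. The list was still called (adjusted p = 0.000807, and adjusted p = 0.484 with an estimated correlation), with 13 of 13 members above 0. The remaining adipocyte scores were 0.81 in HE1 and -0.63 in HE2, against -0.37, -0.58 and -1.57 in Hy1, Hy2 and Hy3. HE2 thus lay below Hy1 and Hy2, and the groups overlapped. Whether these libraries account for all of the difference stays open. With all libraries the call of the adipocyte list was lost without Hy3 or HE3 (0.1 and 0.0549, within 1.88e-06 to 0.861 over all alternatives). In the remaining libraries the cardiac list was also higher in HE (median 0.67, adjusted p = 8.37e-06, and adjusted p = 0.516 with an estimated correlation), so heart muscle in other libraries stays open for both lists. An effect of exercise stays open and untested.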

How the results depend on the processing

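The fits on genes that overlap no other gene, on all genes with values in Hy and HE, without C1, Hy4 and HE3, and without Hy2 and Hy4 were chosen after seeing the data. Limma-voom, RLE factors, no filter and the stricter filter left each count of genes within 1.5 times its value, and so did DESeq2 for Hy against C and HE against C. The 2-fold threshold and the fit on genes that overlap no other gene tested or kept fewer genes by construction. The replicate block in effect left out Hy4 and spent residual degrees of freedom, so its shifts are no clean check of pairing. For the other shifts the cause was not tested.

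For genes higher and lower in Hy against C (2225 and 1625), the 2-fold threshold gave 803 and 331, the replicate block 1112 and 633, genes that overlap no other gene 1183 and 889, the fit without C1, Hy4 and HE3 226 and 134, and the fit without Hy2 and Hy4 683 and 387. Only the 2 groups compared gave 1058 lower. With 1 library left out the counts ran from 1023 to 3175 and from 607 to 2798. In HE against Hy (0 and 0), DESeq2 gave 9 and 42 and the fit without Hy2 and Hy4 1 lower, with 0 to 1 and 0 to 6 when 1 library was left out. Over all 14664 testable genes with values in Hy and HE, 0 were called (536 unadjusted). In HE against C (1734 and 1279), the 2-fold threshold gave 614 and 314, only the 2 groups compared 2667 and 2741, genes that overlap no other gene 924 and 663, and the fit without C1, Hy4 and HE3 342 and 156, with 630 to 2493 and 345 to 2219 when 1 library was left out. Genes called in opposite directions (0) were 27 with DESeq2 and 0 to 6 with 1 library left out.

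Lists called higher and lower in Hy against C (4 and 3) were 0 and 0 with an estimated correlation and 1 and 0 with fry, and 8 were higher without C1, Hy4 and HE3, with 3 to 5 and 2 to 5 when 1 library was left out. In HE against Hy (8 and 8) they were 0 and 0 with an estimated correlation, 0 and 0 with fry, and 4 and 5 on genes that overlap no other gene. There were 13 lower with the replicate block and 16 lower without C1, Hy4 and HE3, with 6 to 11 and 6 to 12 when 1 library was left out. In HE against C (0 and 4), 2 were higher with the replicate block, 4 without C1, Hy4 and HE3 and 2 without Hy2 and Hy4, and 0 were lower with an estimated correlation and 0 with fry, with 0 to 5 and 4 to 6 when 1 library was left out. The unfolded protein response in HE against Hy turned direction without HE1 (adjusted p = 0.429, with 4.29e-06 to 0.429 over the libraries left out) and glucocorticoid-responsive genes without HE2 (0.821, with 7.18e-08 to 0.821).

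Same-numbered libraries of HE did not deviate together with those of Hy (-0.04, 0.06 and -0.02) or of C (-0.10, 0.19 and -0.26), so the replicate block only groups numbers there. With the block 0 genes were called in HE against Hy and 2669 in HE against C, and not every library correlated best with its own number. In Hy against C the block changed no named call beyond those given with their genes. On simulated data of this depth and size, 2-fold changes were called in 45%, 47% and 39% of genes in Hy against C, HE against Hy and HE against C. The simulated spread was the same in all groups, though the largest differences between replicates were in Hy. The shares for comparisons with Hy may thus be too high.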

Other observations

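The tests in this part use lists fixed before the data were examined, and the members named here were chosen after their values were seen. In Hy against C 26.1% of all tested genes were called, 2225 higher and 1625 lower. A count of called members near that share sets no list apart from other genes. Of the 25 HIF target genes, 6 rose and 3 fell in Hy against C with edgeR, and camera did not call the list (adjusted p = 0.65). Ak4, Ankrd37 and Adm rose by 1.91, 1.74 and 1.45 on the log2 scale, while P4ha1, Pfkfb3 and Hk2 had log2 fold changes of -1.32, -1.10 and -0.91. In HE against Hy 0 of the 25 genes passed and the median was -0.08. Of the 11 pericyte genes, 6 rose and 1 fell in Hy against C, and the list was not called (adjusted p = 0.093). Lamc3, Notch3 and Cspg4 averaged 12.1, 106 and 24.5 CPM in C, 64.3, 259 and 58.3 CPM in Hy, and 63.6, 237 and 51.4 CPM in HE. Of the 12 general capillary genes, 4 fell, among them Cd36 from 993 to 531 CPM and Kit from 315 to 152 CPM (list adjusted p = 0.124).

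In the BMP and TGF-beta list, 3 genes rose and 4 fell in Hy against C, and the list was not called (adjusted p = 0.555). Bmpr1a and Tgfbr1, which encode receptors, had log2 fold changes of -0.89 and -0.96, whereas Id1 and Id3, which are targets of BMP signalling, rose by 1.10 and 1.29. Of the 30 extracellular matrix genes, 6 fell and 0 rose in Hy against C, including Col3a1 from 859 to 317 CPM (edgeR unadjusted p = 0.00482), but 0 passed when adjusted over the list alone (list adjusted p = 0.209). Of the 19 circadian genes, 1 rose and 3 fell in Hy against C. Arntl averaged 4.00, 10.6 and 4.47 CPM in C, Hy and HE, and Hlf 34.7, 15.4 and 38.3 CPM, opposite patterns in the same libraries. The time of day of sampling is not given in the labels. The 13 mitochondrially encoded genes had no tested member, and 3 of 8 eosinophil genes were tested. Ddx3y, a Y-linked gene, was between 32.9 and 73.0 CPM in all 10 libraries.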
